A study of Drosophila melanogaster with 6 samples.

How the data were processed

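RNA from male Drosophila melanogaster larvae in the last larval instar was measured on 6 one-colour Affymetrix Drosophila Genome arrays, 1 RNA preparation per array. The mutant group is homozygous for an EMS-induced msl2 allele and the control group is heterozygous for it. Each group has 3 arrays. Per the labels, these are 3 independent preparations per genotype, each from a pool of at least 50 larvae, so the replicate is the pool and not the single larva. Groups and replicate numbers were taken from the sample titles. The titles call the controls wt, while the genotype labels of the same samples give the mutant allele over a wild-type one, so they are called heterozygous here.

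The deposited values are log2 expression values, 1 per probe set, which the authors obtained with RMA (background correction, normalization between arrays and summarization), per the labels. Per the submitters' processing notes the scanner software was GCOS 1.4. The program that ran RMA, its version and the probe set definitions are not given in the sources used here. The values ranged between 2.25 and 14.28 in control replicate 3, and the medians of the 6 arrays lay between 5.88 and 6.06. RMA makes the overall distribution of the arrays alike, so a change of all genes in 1 direction is not visible in these values. Its background model also compresses differences between dim probe sets. For arrays no read depth exists, and the number of arrays limits the precision.

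Probe sets were named through the platform annotation of the array. Of 18952 probe sets, 183 are controls, 13647 have 1 gene symbol, 402 have several and 4720 are unnamed here. Probe sets with several genes or unnamed here were left out of the gene rows. Gene identifiers were looked up in a RefSeq gene table of the assembly named Release 6 plus ISO1 MT, which held 13544 of the 13647. That table supplied symbols, chromosome arms and the order of neighbouring genes. No coordinates are given because the deposited values name no genome build. Where a gene had several probe sets (1094 genes), the one with the highest mean over the 6 arrays was used, which left 11983 gene rows, of which 1869 lie on the X, 2203 on 2L, 2427 on 2R, 2344 on 3L, 2972 on 3R and 65 on chromosome 4. The roX RNAs and w are not analysed here.

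Analyses used R 4.3.3 with limma 3.58.1, and plots were drawn with Python 3.11.15 and matplotlib 3.10.9. The tests, the groups, the gene lists, the naming rule and the other settings to be tried were fixed before the data were examined. Differences of single genes (mutant minus control) were tested with limma (lmFit and eBayes, two-sided) and adjusted by Benjamini-Hochberg over all 11983 gene rows, with a threshold of 0.05. For the chromosome comparison, each gene was centred on its mean over the 6 arrays. The value of an array is then the median over X-linked genes minus the median over genes of 2L, 2R, 3L and 3R, using the brighter 50% of genes by mean log2 value. The group means of that value were compared with a two-sided exact permutation test over arrays, for which the smallest possible p with 3 against 3 is 0.10. Chromosome arms were compared in the same way, each against the other major autosomal arms, with Benjamini-Hochberg adjustment over the arms. The X-linked genes were also tested as a set against autosomal genes with camera (limma), with the correlation between genes estimated from the residuals.

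A total of 23 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, then again with an estimated correlation and with autosomal members only. They cover the MSL complex and its partners, sex determination, fourth-chromosome and heterochromatin factors, salivary glue, fat body and serum proteins, the ecdysone response, larval cuticle, body wall muscle, midgut digestion, testis, Y-linked fertility genes, immune response, hemocytes, heat shock, detoxification, apoptosis and DNA damage, glycolysis, the respiratory chain, the proteasome, the nervous system, imaginal discs and proliferation, and cytoplasmic and mitochondrial ribosomal proteins. Genes named in the text are those with the largest change past the threshold without overlap between the groups, up to 8 in each direction and filled by smallest p where fewer pass. To these come all measured members of the MSL list, up to 4 members of each list past the threshold or else the 2 with the smallest p, and the genotype marker y. Genes named outside this rule are said to have been chosen after their values were seen.

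Signs of RNA quality were taken from 5 pairs of control probe sets that detect the 3' and the 5' part of a fly transcript (actin, eIF-4a and GAPDH, with a second set each for Act5C and GAPDH). The mean 3' minus 5' difference per array is used below. The analysis was tested on simulated data made from the real means and spreads of the 11983 genes, with 200 genes changed and the X-linked genes shifted by -0.3. Of the genes changed by 2 log2 units, 84.8% were called, against 31.3% of those changed by 1 and 2.99% of those changed by 0.5. The simulated X shift was recovered as -0.323, and 14 autosomal genes left unchanged were called. With no change simulated 0 genes were called. Simulated genes varied independently of each other, unlike those on the real arrays.

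Alternatives were leaving out each array, the shared replicate number as a block, other scalings, other filters on dim genes, the median of a gene's probe sets, 1 row per probe set, array weights, an intensity trend with a robust prior, a minimum fold of 1.2, the mean in place of the median, and other correlations for the set tests. A fit with the 3' minus 5' difference as a covariate, and the X shift among genes with a small spread over the mutant arrays, were added after seeing the data.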

Results

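Expression was measured in male larvae homozygous for an msl2 mutation and in heterozygous control males, with 3 arrays per genotype. MSL2 is a subunit of the MSL complex, which binds the single X chromosome of male flies and raises the expression of its genes. The series addresses whether X-linked genes need MSL2 for that raised expression, and whether autosomal genes need it too.

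The mutant arrays differed more among themselves than the control arrays did, and the genes behind this include markers of larval age and of the testis. In mutant replicate 1 most salivary glue genes had low values. Sgs3, Sgs7 and Sgs8, the genes with the largest falls and chosen, like Fbp1, after their values were seen, encode the glue that fixes the puparium and had log2 values of 4.63, 5.62 and 5.35, against 12.22, 13.47 and 12.99 in control replicate 1. Over 8 glue genes the median difference from the control mean was -6.16 in mutant replicate 1 (from -8.00 to -2.18, the last for Sgs5, at 11.30). It was 0.75 in mutant replicate 2 (from 0.40 to 3.47) and 0.23 in mutant replicate 3. The dimmest 25% of genes have means of up to 5.43, and the size of a fall to near that level is approximate. Fbp1, a fat body receptor gene switched on late in larval life, was 5.27 in mutant replicate 1 and between 12.04 and 13.47 in the other 5 arrays. Over all genes, the median SD within the group was 0.284 in the mutants and 0.148 in the controls. Correlations between control arrays were between 0.992 and 0.993, and those between mutant arrays between 0.953 and 0.984. Those between a mutant and a control array were between 0.9646 and 0.9845. Mutant replicate 2 correlated at 0.978 to 0.983 with the controls and at 0.953 and 0.971 with mutant replicates 1 and 3. By this measure the mutant arrays did not form a group apart from the controls. The mean 3' minus 5' difference of control probe sets was 2.19, 1.33 and 1.88 in mutant replicates 1, 2 and 3, and 1.95, 1.80 and 1.85 in the controls. The 3 mutant values thus lay on both sides of the controls (mutant 1.80 ± 0.44 and control 1.87 ± 0.07, SD, n = 3 each, exact permutation p = 0.90).

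**Figure D1:**
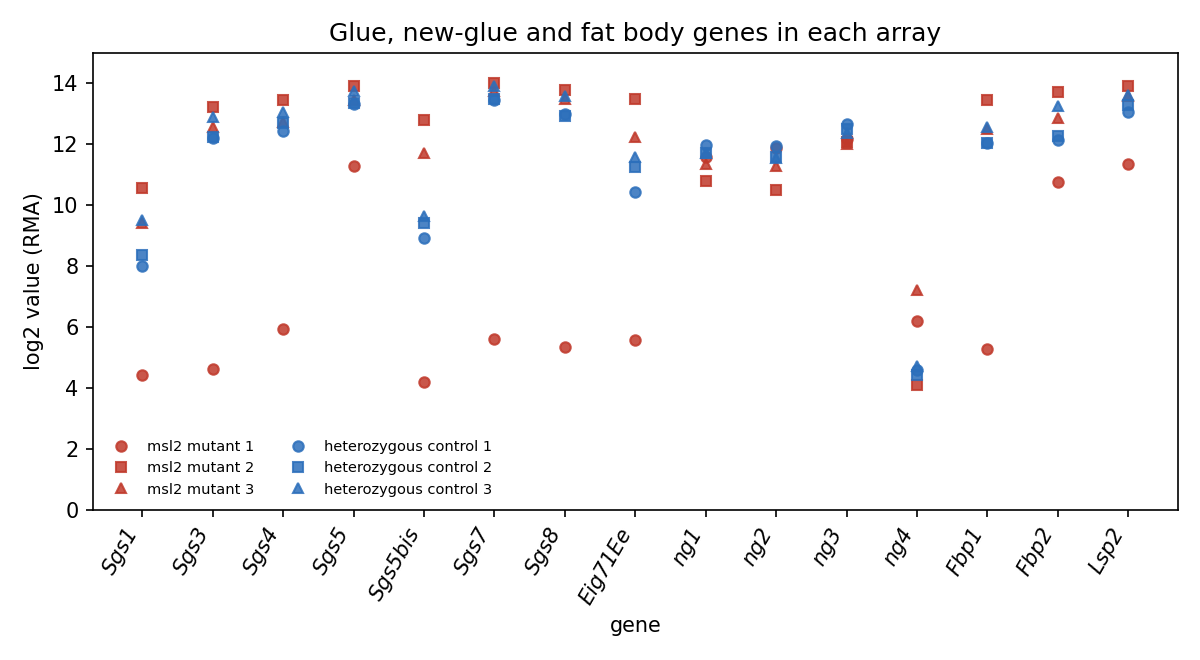
Log2 values (vertical axis, RMA) of glue genes (Sgs genes and Eig71Ee), ng genes and fat body genes (horizontal axis) in each of the 6 arrays, with mutants in red, controls in blue and the replicate number given by the symbol. Sgs3, at 4.63 in mutant replicate 1, is at 12.22 or more in the other 5 arrays, while ng1 lies between 10.79 and 11.98 in all 6.

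X-linked genes were lower in the mutants than in the controls, relative to autosomal genes, in all 3 mutant arrays. For 775 X-linked genes against 5168 genes on 2L, 2R, 3L and 3R (brighter 50% of genes), the X minus autosome value was -0.16 ± 0.08 in the mutants and 0.15 ± 0.03 in the controls (log2, SD, n = 3 each). The difference was -0.31 (SE 0.05), a factor of 0.809 relative to autosomal genes. The median of the X-linked genes alone differed by -0.27. As RMA sets the overall level of the arrays, neither value is an absolute fraction of control expression. The single mutant arrays had -0.25, -0.09 and -0.13 and the control arrays 0.18, 0.15 and 0.11, so that the groups were 0.21 apart at their nearest. The exact permutation test gave p = 0.10, two-sided, the smallest that 3 against 3 arrays allow. As a set, X-linked genes were lower with p = 0.0259 (camera, estimated correlation 0.088), and this p was 0.102 without mutant replicate 1 and 0.0572 without control replicate 1.

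The lower values were spread over most X-linked genes and over the length of the chromosome. Of the 775 X-linked genes, 642 (82.8%) had a log2 change below 0, with a median of -0.27, against 2308 of 5168 autosomal genes (44.7%), with a median of 0.04. All 3 mutant values lay below all 3 control values in 29.9% of X-linked and 6.12% of autosomal genes, and above them in 1.03% and 8.26%. For groups of equal spread chance gives 10% for both directions together, but the mutant spread was larger. When the X-linked genes were divided into 10 parts by gene order, the shift lay between -0.38 and -0.23, and the mutant arrays were below the control arrays in each part. The shift differed with expression level: it was -0.02 in the dimmest 25% of all genes, -0.14 and -0.29 in the following 25% each, and -0.34 in the brightest 25%. Without a filter on dim genes the X shift was -0.175. X-linked genes with the smallest p were CG40486 at -1.86 (SE 0.19), CG14621 at -1.47 (SE 0.18) and CG3719 at -1.04 (SE 0.12), each with a limma adjusted p of 0.105.

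**Figure D2:**
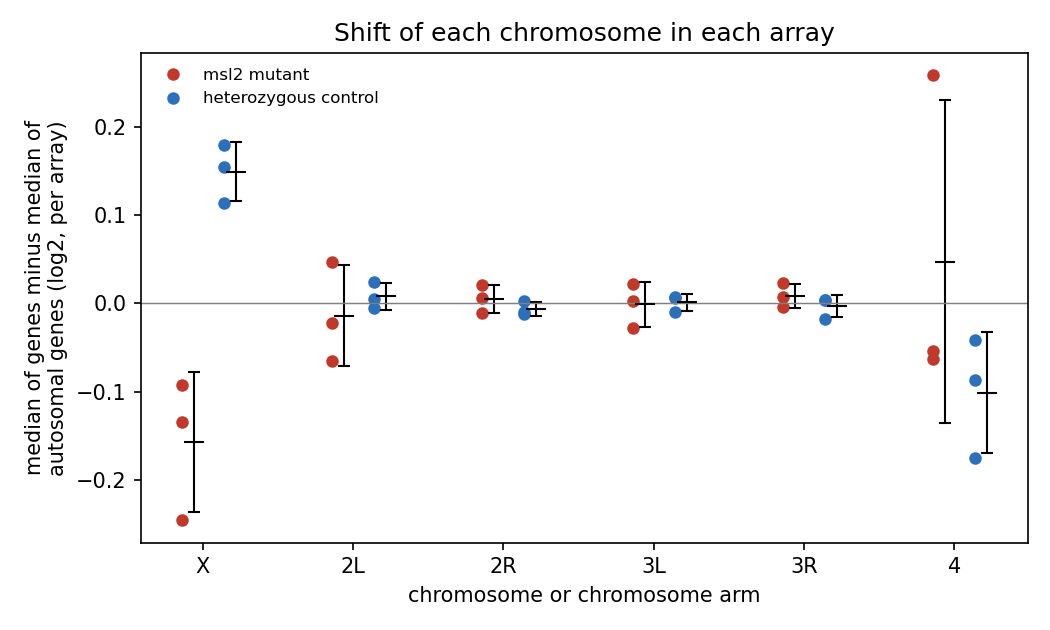
Median over the genes of a chromosome arm minus the median over autosomal genes (vertical axis, log2; for an autosomal arm, over the other major autosomal arms), for each arm (horizontal axis) in each mutant array (red) and control array (blue), brighter 50% of genes. Black bars give the mean and SD of 3 arrays; on the X the mutant arrays lie between -0.25 and -0.09 and the control arrays between 0.11 and 0.18.

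**Figure D3:**
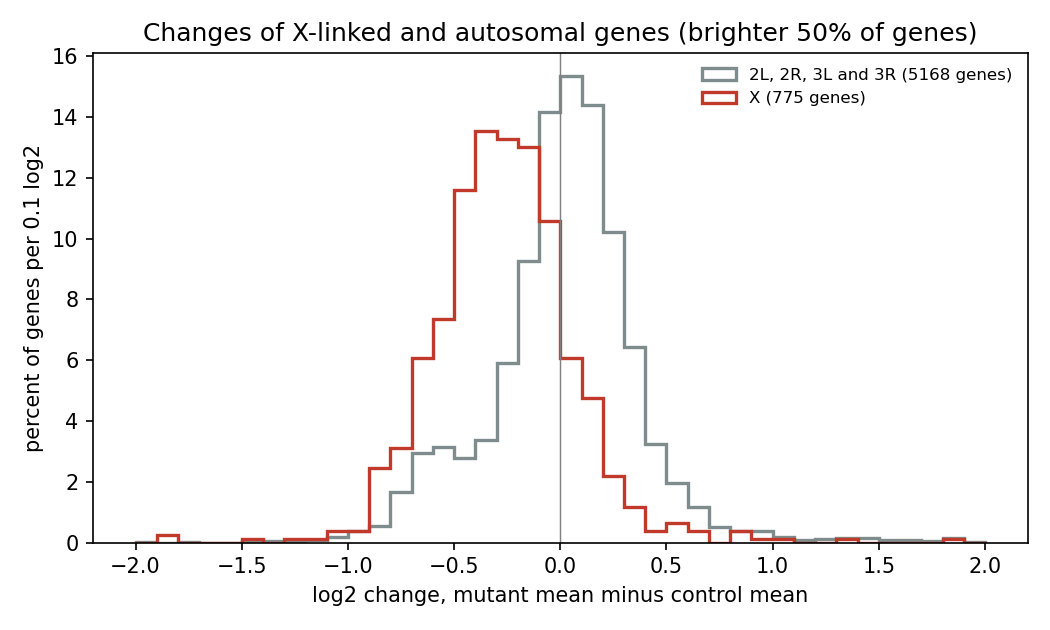
Percent of genes (vertical axis) per 0.1 log2 step of the change, mutant mean minus control mean (horizontal axis), for 775 X-linked genes (red) and 5168 autosomal genes (grey), brighter 50% of genes. The X-linked distribution has its median at -0.27 and the autosomal one at 0.04; 8 X-linked and 20 autosomal genes lie beyond the plotted limits of -2 and 2.

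In the brighter 50% of genes no autosomal arm had mutant arrays apart from control arrays. The shift was -0.02 (SE 0.03) for 2L, 0.01 (SE 0.01) for 2R, 0.00 (SE 0.02) for 3L and 0.01 (SE 0.01) for 3R, with exact permutation p between 0.30 and 0.80. The 32 genes of chromosome 4 had a shift of 0.15 (SE 0.11, exact permutation p = 0.30), with mutant replicate 2 at 0.26 and the other mutant arrays at -0.06 and -0.05. Without mutant replicate 2 the shift of chromosome 4 was 0.06, and that of 2L was -0.05 (SE 0.02). The exact permutation p of this 2L value was 0.10, the smallest possible there. In the brightest 25% of genes the groups were apart, barely, for chromosome 4 (0.20, SE 0.09, 22 genes) and 2R (0.02, SE 0.01), both with the smallest exact permutation p of 0.10 (adjusted 0.25). As sets, tested like the X-linked genes (camera, estimated correlation), 2L, 2R, 3L and 3R had p of 0.807, 0.869, 0.944 and 0.881. The exact test cannot reach 0.05 in this design, and RMA sets the overall level of the arrays, so the autosomal values are relative to each other.

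Single genes rarely passed the test over all 6 arrays. CG11893 (3R) fell by 5.05 (SE 0.30, limma adjusted p = 0.0103), from 9.47 ± 0.47 in the controls to 4.42 ± 0.39 in the mutants (SD, n = 3 each), and CG31676 (2L) fell by 1.98 (SE 0.16, limma adjusted p = 0.0411). No X-linked gene passed, and 0 genes rose. The mutant values of CG11893 are in the range of the dimmest 25% of genes, so the size of its fall is approximate. At an unadjusted p under 0.05, 463 genes were higher and 558 lower, and on the X 37 were higher and 252 lower. Over all genes, 13.9% had groups that did not overlap, against 10% by chance for groups of equal spread. The spread was not equal, with a median SD of 0.284 in the mutants and 0.148 in the controls. Genes also vary together, so the difference from 10% is no measure of a genotype effect. The count depended on mutant replicate 2: without it 335 genes were higher and 948 lower by limma, including 243 of the 1869 X-linked genes and between 6.26% and 8.81% of the genes of each major autosomal arm. With limma's array weights 441 genes were higher and 1012 lower, in a fit where mutant replicates 1, 2 and 3 had weights of 0.415, 0.175 and 3.15, so that the mutant mean rests mainly on mutant replicate 3. Without mutant replicate 1 or control replicate 1 the count of lower genes was 1, and without mutant replicate 3, control replicate 2 or control replicate 3 it was 0. CG11893 passed without mutant replicate 1, mutant replicate 2 or control replicate 1, and its limma adjusted p was 0.122, 0.116 and 0.0887 without mutant replicate 3, control replicate 2 and control replicate 3. CG31676 passed without mutant replicate 2 (limma adjusted p = 0.00612), and its adjusted p was 0.106 and 0.498 without mutant replicates 1 and 3 and 0.193, 0.305 and 0.229 without control replicates 1, 2 and 3. With the 3' minus 5' difference as a covariate, chosen after seeing the data, 131 genes were higher and 139 lower.

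Among genes below the threshold, several autosomal ones had mutant and control values that did not overlap, and those that were higher include digestive enzymes and chitinases. Mal-A6, a maltase, was higher by 3.20 (SE 0.36), tobi, an alpha-glucosidase gene that responds to insulin-like signals, by 2.53 (SE 0.33), Cht4 by 2.17 (SE 0.27), CG31089 by 2.10 (SE 0.26), Mur89F, a mucin-related gene, by 1.54 (SE 0.19), CG42822 by 1.49 (SE 0.18), the lysozyme gene LysP by 1.42 (SE 0.19) and Cht9 by 1.30 (SE 0.16). Cyp6a17, a cytochrome P450 gene, was -4.46 (SE 0.49; approximate, as its mutant values are dim), CG10140 -1.08 (SE 0.12) and Jhbp14, of the juvenile hormone binding protein family, -0.94 (SE 0.12). Their limma adjusted p values were 0.105 or 0.117. Each of these genes passed the threshold without mutant replicate 2, with a limma adjusted p of 0.00886 for Mal-A6 and 0.00518 for Cyp6a17. For Cyp6a17 it was 0.075 and 0.498 without mutant replicates 1 and 3, and 0.472, 0.577 and 0.396 without control replicates 1, 2 and 3. Of the 71 genes named by the rule, 30 newly passed without mutant replicate 2 and 0 without any other single array.

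No difference was detected in the mRNA of msl-2 itself, at 5.11 ± 0.34 in the mutants and 5.06 ± 0.17 in the controls (difference 0.05, SE 0.21, limma adjusted p = 0.96). Its probe set was among the dimmest 25% of genes, where the X shift was -0.02 against -0.34 in the brightest 25%. The allele is chemically induced, and a probe set for the transcript does not measure whether protein is made, so this value does not check the genotype. Of the 13 measured members of the MSL list, 0 passed the threshold over all genes and 0 adjusted over the list alone. The gene of another subunit, msl-1, was higher by 0.60 (SE 0.22, limma adjusted p = 0.55) and Unr, which represses msl-2 translation in females, by 0.57 (SE 0.22, limma adjusted p = 0.56), both without overlap between the groups. Without mutant replicate 2 they were at 0.40 and 0.34. The other members were nsl1 at 0.50 (0.20 without mutant replicate 1), msl-3 at -0.12, mle, an RNA helicase, at 0.01, mof, the acetyltransferase, at 0.06, Clamp at 0.10, JIL-1 at 0.07, Chro at 0.03, pzg at 0.01, Rcd5 at -0.04 and Nup153 at 0.26 (0.14 without mutant replicate 2). Like msl-2, the genes mle, mof and JIL-1 were among the dimmest 25% of genes, so a difference in them may be compressed. The list as a whole had a camera adjusted p of 0.186, and of 0.0166 without mutant replicate 3 and 0.0205 without control replicate 1, at the preset correlation; with an estimated correlation (0.488) it was 0.879. The marker y differed by 0.01 (SE 0.63), with an SD of 1.33 among the mutants, and by 0.77 without mutant replicate 2.

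Most genes of the respiratory chain had mean values below the controls, by a test that holds only at the preset correlation. Of 43 measured members of the respiratory chain and ATP synthase, 41 had a change below 0 (median -0.22, camera adjusted p = 4.86e-10). Its adjusted p = 0.879 with an estimated correlation. The 24 members without overlap between the groups were all lower; 6 were lower adjusted over the list alone and 0 over all genes. The medians of the list were -0.15, -0.40 and -0.18 in mutant replicates 1, 2 and 3 (exact permutation p = 0.10). ND-ASHI of complex I was -0.76 (SE 0.14) and UQCR-14 of complex III -0.61 (SE 0.13), both X-linked and both past the threshold without mutant replicate 2 (limma adjusted p of 0.0295 and 0.0392). Only 8 members are X-linked, and with autosomal members alone the camera adjusted p was 2.67e-08 at the preset and 0.85 at the estimated correlation. Of 69 mitochondrial ribosomal protein genes, 63 were below 0 (median -0.19, camera adjusted p = 1.19e-08). Here the adjusted p = 0.879 with an estimated correlation, 10 were lower adjusted over the list alone and 0 over all genes, and the X-linked members mRpL49 and mRpS14 had -0.81 and -0.70 (limma adjusted p of 0.0289 and 0.0323 without mutant replicate 2). The list medians were 0.07, -0.49 and -0.13 in mutant replicates 1, 2 and 3, the first above all 3 controls (exact permutation p = 0.40). Without mutant replicate 2, which also had the lowest 3' minus 5' difference and the highest glue median, the camera adjusted p was 0.454.

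Testis genes had lower values in mutant replicates 1 and 3. Of 33 measured genes of the testis and spermatocytes, 31 were below 0 (median -0.54, camera adjusted p = 3.38e-07), with adjusted p = 0.879 with an estimated correlation. The list medians were -1.04, 0.12 and -0.80 in mutant replicates 1, 2 and 3 (exact permutation p = 0.30). The meiotic arrest gene comr was -0.60 (SE 0.15) and nht, a testis subunit of a general transcription factor, -0.65 (SE 0.21), and both passed without mutant replicate 2 (limma adjusted p of 0.0289 and 0.0226). Adjusted over the list alone 0 passed, as over all genes. This list and the respiratory chain list stayed under 0.05 at the preset correlation without any 1 of the 6 arrays.

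The lists for midgut digestion, detoxification and the ecdysone response were higher by camera at the preset correlation, with adjusted p of 0.00763, 0.00763 and 0.0098. For each of the lists the adjusted p = 0.879 with an estimated correlation. Over the list medians of the arrays the exact permutation p was 0.70 for midgut digestion, 0.30 for detoxification and 0.30 for the ecdysone response. In midgut digestion 21 of 37 members were above 0 (median 0.06), 6 were higher adjusted over the list alone and 0 over all genes, led by Mal-A6 and Mal-A8 (3.07, SE 0.48). In detoxification 35 of 52 were above 0 (median 0.18), and 2 were higher and 1 lower adjusted over the list alone, against 0 over all genes. Its members with the smallest p went both ways, Cyp6d5 at 1.24 (SE 0.20) and Cyp6a17 at -4.46. In the ecdysone list 21 of 30 were above 0 (median 0.22), with ImpE1, an ecdysone-inducible gene of imaginal discs, at 1.80 (SE 0.25) and MsrA at 0.87 (SE 0.22). Adjusted over the list alone 1 was higher, against 0 over all genes. Without mutant replicate 2, Mal-A8, Cyp6d5, ImpE1 and MsrA passed (limma adjusted p of 0.00942, 0.028, 0.0226 and 0.0346). The ecdysone list had a median of 0.46 in mutant replicate 2 and of -0.01 in mutant replicate 1, and its adjusted p was 0.101 without the former and 0.136 without mutant replicate 3. Midgut digestion had an adjusted p of 0.961 without control replicate 1. For detoxification the value was 0.0503, 0.0593 and 0.076 without mutant replicate 1, mutant replicate 3 and control replicate 1.

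The other lists did not pass at the preset correlation. Salivary glue had a median of -0.58 (10 of 12 below 0, camera adjusted p = 0.086), with ng3 at -0.43 and ng1 at -0.57, and imaginal discs and proliferation 0.10 (21 of 26 above 0, 0.086), with RnrL at 0.43 and en at 0.60. The proteasome had 0.15 (23 of 27 above 0, 0.0958), with Rpn2 at 0.39 and the X-linked REG at -0.28, and with a list median of 0.66 in mutant replicate 2. Without mutant replicate 2, en was at 0.22, Rpn2 at 0.17 and ng1 at -0.34. The glue list medians were -4.66, 0.52 and 0.13 in mutant replicates 1, 2 and 3, so its lower median rests on mutant replicate 1. Without that array glue was higher (adjusted p = 0.0503), and without mutant replicate 3 lower (0.0131). The proteasome had 2.17e-05, 0.0314 and 0.0159 without mutant replicate 1, mutant replicate 3 and control replicate 3, and without mutant replicate 2 it was lower (0.281). Proliferation had 0.00258, 0.019 and 0.016 without mutant replicate 1, mutant replicate 3 and control replicate 1. The proteasome also passed with the autosomal median of each array subtracted (0.046) and with autosomal members alone (0.0294), and proliferation after a further quantile normalization (0.039), all at the preset correlation. With an estimated correlation both lists had an adjusted p of 0.879, and the autosomal members of the proteasome 0.85.

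Medians of further lists that did not pass were 0.08 for glycolysis (adjusted p = 0.191; tobi, and sima at 0.62), -0.12 for body wall muscle (0.294; Mlc2 at -0.90 and Mlp60A at -0.25) and 0.12 for the nervous system (0.34; nSyb at 0.33 and VGlut at 0.26). Without control replicate 1 glycolysis had an adjusted p of 0.0205 and the nervous system 0.0167, and without control replicate 3 muscle had 0.0276, at the preset correlation; with an estimated correlation each of the 3 had 0.879. Medians were 0.18 for apoptosis and DNA damage (0.351; puc at 0.35 and mre11 at -0.33), 0.08 for sex determination (0.403; fl(2)d at 0.45 and ix at 0.16) and -0.14 for fourth-chromosome and heterochromatin factors (0.466; Pof at -0.63 and HP1b at -0.18). Y-linked fertility genes had -0.07 (0.517; Ppr-Y at -0.14 and kl-2 at -0.10), heat shock genes -0.05 (0.77; stv at -0.31 and Hsp60B at -0.46) and hemocyte genes 0.09 (0.798; atilla at -0.33 and Sr-CI at -0.45). In 4 lists the median and the test had opposite signs: larval cuticle (median 0.13, mean -0.01, adjusted p = 0.77; Cht5 at 1.18 and Cpr67Fa1 at -1.30), fat body and serum proteins (median -0.04, 0.77; Lsd-2 at 0.39 and Lpin at 0.23), immune response (median 0.04, mean -0.08, 0.959; PPO3 at -2.01 and lectin-24A at -1.57) and cytoplasmic ribosomal proteins (median 0.03, mean -0.05, 0.798; RpL37-2 at -0.62 and RpL22-like at -0.53). Adjusted over the list alone, 3 immune genes were lower, 1 cuticle gene was higher and 1 lower, 1 glycolysis gene was higher, and 0 passed in the remaining lists that did not pass, glue, proliferation and proteasome included; over all genes 0 passed in each. Without mutant replicate 2, Pof was at -1.02 (limma adjusted p = 0.0292), and tobi, Hsp60B, PPO3, lectin-24A, RpL37-2 and RpL22-like passed as well (0.0085, 0.0315, 0.0272, 0.0272, 0.0312 and 0.0445). In the same fit HP1b was at -0.33, Lsd-2 at 0.16, mre11 at -0.15 and ix at 0.04. Without mutant replicate 1, Pof was at -0.32, HP1b at -0.05, fl(2)d at 0.29, Sr-CI at -0.22 and Hsp60B at -0.25. The cuticle median was -0.81 in mutant replicate 2 and 0.28 in mutant replicate 1, and its camera adjusted p was 0.04 (higher) without mutant replicate 2 and 0.0314 (lower) without mutant replicate 3, at the preset correlation; over all 6 arrays it was 0.92 with an estimated one.

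**Figure D4:**
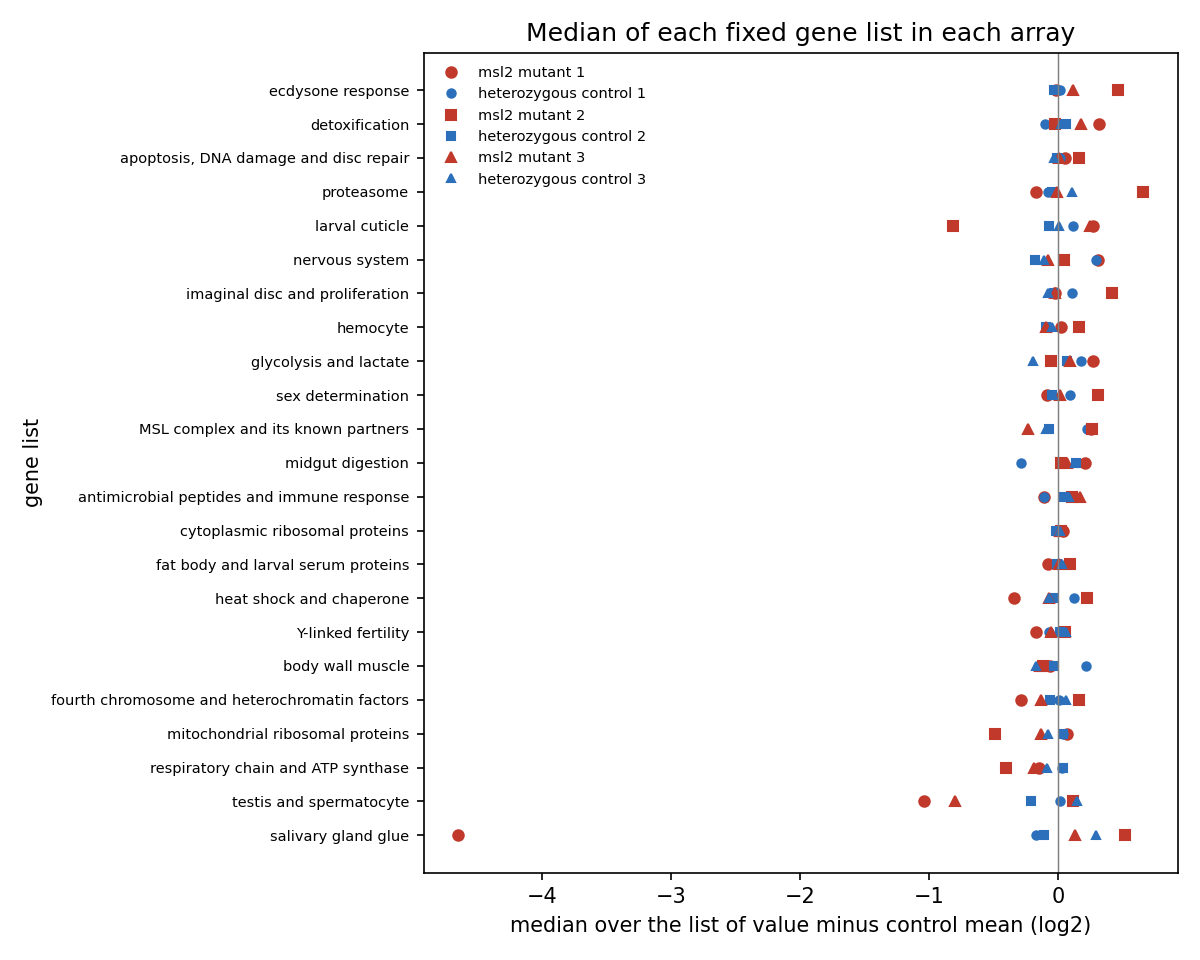
Median over the members of each of the 23 gene lists of the value minus the control mean (horizontal axis, log2), for each list (vertical axis), in mutant (red) and control (blue) arrays, with the replicate number given by the symbol. Salivary glue lies at -4.66 in mutant replicate 1, and testis genes at -1.04 and -0.80 in mutant replicates 1 and 3 against 0.12 in mutant replicate 2.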

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

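The tests in this part on 3' bias, brightness, genes with a small spread, the ng genes, Fbp1 and neighbours were chosen after the results were seen. None of them was a prediction made in advance.

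Probe sets that belong to no gene row, either unnamed here or listed with several genes, were tested in a separate fit over 18769 probe sets (limma, 1 row per probe set), and 4 of them passed. Probe set 1630934_at was higher in the mutants by 3.48 (SE 0.29, limma adjusted p = 0.0268), probe set 1641367_at by 1.81 (SE 0.16, 0.0327) and probe set 1639374_s_at, listed with several genes, by 1.70 (SE 0.13, 0.0205). Probe set 1624321_at was lower, at -1.54 (SE 0.12, limma adjusted p = 0.0205). Their lowest and highest mutant values did not overlap the controls.

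The lower level of X-linked genes was set against 3 technical or indirect explanations. RNA integrity predicts that mutant arrays with a smaller 3' minus 5' difference than the controls have X values at or above the controls. However, mutant replicate 2, with the smallest difference, has a lower X value than every control, and the groups are 0.205 apart. Among the mutants the X value did follow that difference, with -0.09, -0.13 and -0.25 at 1.33, 1.88 and 2.19 in replicates 2, 3 and 1. The gap between the groups thus does not decide whether RNA integrity adds to the size of the shift. Brightness of X-linked genes predicts a shrinking shift against autosomal genes of like brightness, and it was -0.308 over 200 draws. Within brightness classes the shift of the brighter genes had already been -0.29 and -0.34, so the draws repeat that comparison and are no separate test. Compression of dim probe sets makes differences smaller, so the draws do not decide on it. Differences between mutant arrays in age or tissue predict a shrinking shift among genes with a small spread over the mutant arrays. It was -0.315 (SE 0.04) for 409 X-linked genes. An age or tissue difference shared by all 3 mutant pools leaves that spread small, so the test cannot decide on such a difference. A loss of the X-wide action of MSL2 remains a hypothesis consistent with these values.

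Salivary glue genes were low in mutant replicate 1 alone. Less salivary gland RNA in that preparation predicts that ng1, ng2 and ng3, from the same gland, are as low, but their median difference from the control mean was -0.221. These genes are no fixed measure of gland RNA: in mutant replicate 2, with a glue median of 0.75, they were at -1.02, -1.20 and -0.44. A further gene, ng4, was not in the test and was at 1.62, -0.48 and 2.65 in mutant replicates 1, 2 and 3. The test therefore does not decide on the amount of gland RNA. Larvae younger than in the other preparations predict that Fbp1, a fat body gene, is low as well, and its difference from the lowest control was -6.77 (control SD 0.298). A candidate explanation is that larvae in mutant replicate 1 were younger, and whether the genotype delays development was not tested.

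CG11893 and Cyp6a17 stood at -5.05 and -4.46 in the mutants. They lie on 3R and 2R, and their mutant means of 4.42 and 4.31 are in the range of the dimmest 25% of genes, so the values show large falls but not their exact size. A deletion or sequence variant carried by the mutant stock, apart from msl2, may account for these values: the medians over the 10 nearest measured genes were at most 0.386 in size, and the mutant values of both genes lay below the array medians. This cannot be told apart from a shutdown of the genes, through loss of MSL2 or otherwise, because no genotype other than the array values was used here.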

How the results depend on the processing

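The tests with the 3' minus 5' covariate, with small-spread genes, and of the counts of genes and of lists over other splits were chosen only after the result was seen. The X against autosome shift kept its direction under all 15 other settings, from -0.34 in the brightest 25% of genes to -0.175 with no filter. Subtracting the autosomal median of each array and using the block cannot change this shift (-0.306 in both), so these settings are no check of it. The camera p of the X-linked set stayed below 0.05 except without mutant replicate 1 (0.102), without control replicate 1 (0.0572) and with the covariate (0.0509). Leaving out 1 array at a time gave shifts between -0.335 and -0.262 and camera p between 0.0129 and 0.102. With the covariate the shift was -0.316. Genes higher ranged from 0 to 335 and genes lower from 0 to 948 without 1 array. With the replicate number as a block 0 genes were lower, and the shift was -0.306 (exact sign-flip p = 0.25, the smallest for 3 pairs); the numbers did not pair the arrays, as same-number deviations correlated at 0.19, -0.27 and 0.11. Lower genes were 0 among the brighter 50% of genes, 1 with trend and robust, 1 with a minimum fold of 1.2, 1012 with array weights (441 higher) and 139 with the covariate (131 higher). With 1 row per probe set 3 were higher. Lists higher ranged from 3 to 5 and lists lower from 2 to 5 without 1 array. With an estimated correlation 0 lists were higher and 0 lower, and among brighter genes 1 was higher. Shares of X-linked genes below 0 ranged from 76.9% to 85.4% and of autosomal genes from 40.1% to 49.6% without 1 array, and the X-linked share was 69.4% with no filter and 85.8% in the brightest 25%. Brighter X-linked genes past the threshold ranged from 0 to 139 and autosomal from 0 to 379 without 1 array, the autosomal being 0 with the block and in the brightest 25%, and 2 with the median of probe sets and with no filter. The shifts of 2L, 2R, 3L and 3R were near 0, and each changed sign in at least 1 setting, while that of chromosome 4 did not: 2L from -0.0471 to 0.00477 and 2R from -0.000263 to 0.0171, 3L from -0.0121 to 0.00876, 3R from 0.00414 to 0.0174 and chromosome 4 from 0.0552 to 0.209 without 1 array. For 3L it was 0.000956 with the median of probe sets and 0.00453 with no filter, and in the brightest 25% 0.0157 for 2L and -0.00307 for 3R. The cause was not tested. With the block the salivary glue list was lower at a camera adjusted p of 0.0271, at the preset correlation. Without the block and with an estimated correlation its camera adjusted p was 0.879. With gene values quantile normalized again no list median changed sign. Signal over background was not measured; in the dimmest 25% of genes the X shift was -0.02.

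Too few splits of the 6 arrays exist (10) for a share under 0.05. The real split gave 2 genes past the threshold and the highest other 1, with 1 split at or above the real one. At an unadjusted p under 0.05 the real split gave 1021 genes and the highest other 1921, with mutant replicates 1 and 3 and control replicate 2 on one side, so that column does not set the genotypes apart from other structure among the arrays. It gave 6 lists and the highest other 10, with all 10 splits at 6 or more. The p of the X-linked set was 0.0259 and the lowest other 0.18, and the X minus autosome difference in the share below 0 was 38.2 percentage points and the highest other 31.8.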

Other observations

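The comparisons in this part, those with the 3' minus 5' difference included, were chosen only after the results were seen.

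The maltase genes of one cluster on 2R, alpha-glucosidases that release glucose from starch and sugar, mostly had higher values in the mutants, a group chosen after its values were seen. Of 8 measured members, 6 had mutant values above all control values, with Mal-A1 at 3.06 (SE 0.52), Mal-A8 at 3.07 (SE 0.48), Mal-A6 at 3.20 (SE 0.36), Mal-A4 at 1.75 and Mal-A3 at 1.13, and Mal-A7 between Mal-A4 and Mal-A1. Mal-A2 and Mal-A5, at 0.32 each, overlapped. The 5 other measured genes within 50 kb had a median of 0.03, and none of them lay above the controls. Off this cluster, tobi was at 2.53 (approximate, as its control values are dim) and Amyrel, an amylase-related gene, at 2.25. None of these passed the threshold over all 6 arrays. In each of the 6, mutant replicate 2, with the lowest 3' minus 5' difference, had the lowest of the mutant values. That array also had the highest glue median (0.75, from 0.40 to 3.47 over 8 genes) and Fbp1 at 1.25 above the control mean. RNA quality and larval age can therefore not be told apart in it.

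The autosomal changes have a shoulder between -0.9 and -0.4, noticed in the plot of changes. It holds 573 of the 5168 brighter autosomal genes (11.1%), against 373 between 0.4 and 0.9. Of the 22 brighter genes of the testis list, 18 lie in it. The median of the 573 genes was -1.06 in mutant replicate 1, 0.05 in mutant replicate 2 and -0.73 in mutant replicate 3.

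Across the 6 arrays the first principal component (56.9% of the variance) had Pearson r = -0.811 with the 3' minus 5' difference (exact permutation p = 0.0556, adjusted 0.111) and Spearman rho = -0.714 (exact permutation p = 0.136, adjusted 0.272), 1 of 2 relations computed. The X minus autosome value had r = -0.121 (exact permutation p = 0.828, adjusted 0.828) and rho = -0.257 (exact permutation p = 0.658, adjusted 0.658). This second relation pools 2 genotypes whose X values lie apart, so it cannot show a relation within a genotype. Among the mutants the X value was -0.25, -0.13 and -0.09 at differences of 2.19, 1.88 and 1.33. Among the controls it was 0.18, 0.11 and 0.15 at 1.95, 1.85 and 1.80, without such an order. With both mutant replicates 1 and 2 left out, r was -0.10 for the first relation and -0.0229 for the second, so the first rests on those arrays.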
